A study of Mus musculus with 3 samples.

How the data were processed

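Gene expression was measured in peritoneal macrophages of male Swiss albino mice on 3 one-colour Agilent whole-genome mouse arrays, 1 for each of 3 groups of 10 animals aged 8 weeks. Per the labels' protocols, every mouse received 125 µg lipopolysaccharide into the peritoneum on day 0. On day 4 the control group received 100 ng of the phorbol ester TPA, and the other groups received TPA with 35 or 70 nmol of potassium dichromate, a hexavalent chromium salt. Cells were washed out of the peritoneum 4 days later. The sample labels themselves give the doses as 35 and 70 nmol of Cr(VI), that is, of hexavalent chromium. The labels do not settle whether the RNA on an array came from 1 animal or from a pool. Lipoic acid, named in the series title, was on none of the arrays analysed here.

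Per the file headers, the authors extracted spot intensities with Agilent Feature Extraction version 10.5.1.1, which subtracted background and corrected spatial trends, and the probe positions belong to mouse genome build mm8. The deposited intensity columns used were the processed signal, its error, and the mean and local background signals. A spot was well above background by the scanner software's own flag, which the file headers set at a multiple of 13. The authors' deposited value table holds log2 values. Set against the scanner files, each of its columns equalled the log2 processed signal minus 1 constant (8.00, 7.61 and 7.67 for control, 35 and 70 nmol), within 0.01 for 99.8%, 99.8% and 99.9% of the probes well above background. Its column medians were -3.60, -3.74 and -3.78. Scale and direction are thereby known, and genes were not centred.

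The log2 processed signal was scaled here by subtracting each array's 75th percentile over its 43379 spots that are not controls (8.07, 7.69 and 7.74). Flagged outlier spots were left out, and the spots of a probe were averaged, which gave 41174 probes. Probes were named through their accession where the RefSeq table of assembly GRCm38.p6 held it (24375 probes). Otherwise the symbol or a unique synonym was used, and 8072 probes kept the name in the file. A gene's value was that of its brightest probe among those well above background on at least 1 array, which left 14564 genes. A gene counted as measured in a comparison when that probe was well above background on both arrays and neither saturated nor an outlier. Where no probe of a gene was well above background on the dimmer array, a fold is given as a bound. It sets the brighter signal against the higher of the dim probe's own signal and the lowest signal among probes well above background on that array.

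With 1 array per group, no test was possible and no p-value is given. The rule counted genes that differed at least 2-fold. The spread quoted beside single genes is technical: between repeated spots of a probe on an array, between 2 probes of a gene, and the scanner software's own error. It leaves out the spread between animals. Before the data were examined, 51 gene lists were fixed (34 for functions and 17 for cell types), with 906 of 915 entries on the array. For each list, the shift is the median log2 difference of its measured members minus the median of all measured genes. Its percentile is taken among 10000 random lists of the same size matched on expression in 20 bins, as a description of these arrays. The standard deviation of a shift came from 1000 bootstrap draws of its members.

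The rule for named genes was fixed before the data were examined. It took the 10 largest differences each way against the control, and 5 each way between doses, among genes with a symbol. The brighter array had to lie at or above the median of probes well above background, and a gene's other probes had to differ the same way. It added up to 4 members of each list with the largest difference at either dose, up to 5 genes each way seen on 1 array only, and 16 genes named in any case. Of the genes measured at 70 nmol against the control, 1652 had no symbol and were counted without being named. Not every gene that the rule selects is reported here.

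Alternatives were normexp background correction (offset 50), quantile and cyclic loess normalisation, scaling on the median of detected probes, a looser and a stricter filter on dim probes, the mean over a gene's probes, the deposited value table, and thresholds of 1.5-fold and 3-fold. Scaling on spike-in RNA (4 of 10 spike-in probes, between 8 and 14 on the log2 scale) and counts without liver and erythroid genes were chosen after seeing the data. The steps were tested on simulated data for 70 nmol against control, with spot error only, over 13857 genes. Of 50 genes changed 2.5-fold, 98% passed the 2-fold rule. All 50 changed 3-fold and all 50 changed 4-fold passed, as did 0 of 50 changed 1.5-fold and 0 of 13657 unchanged genes. R 4.3.3 with limma 3.58.1 was used for normalisation, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for the rest.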

Results

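Transcript levels were compared in mouse peritoneal macrophages taken 4 days after hexavalent chromium was given at 35 or 70 nmol with the phorbol ester TPA, or after TPA alone as the control. All mice had received lipopolysaccharide beforehand to draw macrophages into the peritoneum. There was 1 array per group, so no difference below has a replicate check, and the number of arrays limits the precision. Of 41174 probes, 20201 (49.1%) were well above background on the control array, 18908 (45.9%) at 35 nmol and 18566 (45.1%) at 70 nmol. Repeated spots of a probe on an array had a median standard deviation of 0.041, 0.043 and 0.035 (log2) on these arrays. The 3 arrays shared a slide and a scan, and the position on the slide cannot be told apart from the group. All differences are log2 unless a fold is named, and they cover these arrays only.

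The first question was what 70 nmol of chromate does to these cells. Chemokines that attract T cells and monocytes were among the named genes with the largest differences from the control. Cxcl9 was 6.47-fold higher (2.69), Cxcl10 6.08-fold (2.61) and Ccl8 2.58 on the log2 scale. The Cxcl9 probe lies on chromosome 5, from 93398365 to 93398424 in the positions the array design gives on build mm8. Of 12541 measured genes, 204 were at least 2-fold higher and 136 at least 2-fold lower than in the control. Between 2 probes of a gene, the difference varied by a median of 0.16 (3089 genes). The median scanner error of a difference was 0.21.

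The interferon response list was higher nearly throughout at 70 nmol. Of its 31 measured members, 30 lay above the median of all genes and 8 were at least 2-fold higher, with a list shift of 0.67 ± 0.08 (bootstrap SD) at percentile 100 of the matched random lists. Ifit2 was 1.76 higher, Isg15, a ubiquitin-like protein induced by interferon, 1.32, and Ifit3 1.31. Genes of antigen presentation lay higher by less. The list of MHC class II genes shifted by 0.29 ± 0.10 (percentile 99.7, 8 members), with H2-DMb1 at 0.56 and Ciita, its master regulator, at 0.41. The MHC class I list shifted by 0.24 ± 0.06 (percentile 99.4, 10 members), with Tap1 at 0.41. The inflammatory cytokine list had a shift of -0.02 ± 0.05. In it Tnf differed by 0.90, Il6 by -0.59 and Il1b by 0.09.

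Chemokines did not move as 1 group. Among 14 measured members at 70 nmol, 5 were at least 2-fold higher and 1 at least 2-fold lower, and the shift of 0.21 ± 0.56 was smaller than its standard deviation. Ccl2, which attracts monocytes, was 1.76 higher. The alternative macrophage activation list shifted by 0.53 ± 0.20 (percentile 100, 16 members), with 4 genes at least 2-fold higher and 2 at least 2-fold lower. Mrc1, the mannose receptor, was 1.59 higher, Pparg 1.30 and Retnla 1.23, whereas Alox15, a lipoxygenase of resident peritoneal macrophages, was 1.65 lower on the log2 scale (-1.65). Arg1 differed by 0.79.

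Markers of other cells moved with these groups at 70 nmol. The fibroblast list shifted by 1.47 ± 0.37 (percentile 100), and 4 of its 5 measured genes were at least 2-fold higher. The collagen-binding proteoglycan Dcn was 2.06 higher, and the collagens Col3a1, Col1a2 and Col1a1 were 1.95, 1.51 and 1.30 higher. Gas6, a ligand of Axl and Mertk, was 1.93 higher. Monocyte and small peritoneal macrophage markers shifted by 0.57 ± 0.11 (percentile 100, 8 members), with F13a1 at 1.24 and Ccr2, the receptor that brings monocytes into tissue, at 0.76. Large peritoneal macrophage markers shifted by -0.98 ± 0.20 (percentile 0), and 4 of 11 were at least 2-fold lower. Among them Garnl3 differed by -1.30, Nt5e by -1.15, Itga6 by -1.11 and Gata6, the transcription factor of these cells, by -1.08. Another Gata6 probe differed the opposite way, by 0.56. Mast cell markers shifted by -1.45 ± 0.20 (percentile 0), and 6 of 8 were at least 2-fold lower, among them the proteases Cma1 at -1.74, Cpa3 at -1.73 and Mcpt4 at -1.70. B cell markers shifted by -0.38 ± 0.03 (percentile 0.01, 11 members), with Fcer2a at -1.02. The general macrophage list shifted by 0.06 ± 0.11, with Adgre1 at -0.51 and Fcgr1 at 0.76.

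Genes of the metal, oxidant and DNA damage responses differed less at 70 nmol. The metal handling list shifted by 0.19 ± 0.09 (percentile 99.3, 13 members). The metallothioneins Mt2 and Mt1 differed by 0.79 and 0.15, the zinc exporter Slc30a1 by 0.89 and ceruloplasmin, Cp, by -1.07. Another Slc30a1 probe gave 0.37. The NRF2 target list shifted by 0.14 ± 0.09 (percentile 97.7, 19 members), and none of its measured members differed 2-fold. Hmox1, heme oxygenase, differed by 0.95 and Srxn1 by 0.56, though another Srxn1 probe gave -1.16. Nqo1, Gclm and Nos2 were not well above background on any of the 3 arrays. The p53 target list shifted by 0.07 ± 0.08 (22 members), with Cdkn1a at 0.66, Mdm2 at 0.31, Ccng1 at 0.01 and Gadd45a at -0.78. In that list 14 members lay above the median of all genes and 8 below. DNA repair genes shifted by -0.08 ± 0.03 (38 members, percentile 15.7), with Ogg1, which removes oxidised guanine, at 0.57. In the list of tumour suppressors and CDK inhibitors (shift -0.10 ± 0.05), Cdkn2b differed by -1.25 and Cdkn1c by -1.08. In the proto-oncogene list (0.13 ± 0.10), Maf was 1.23 and Fos 1.05 higher, Jun differed by 0.96 and Ccnd1 by 0.95, and Myc by -0.19. The immediate early list shifted by 0.21 ± 0.10 (percentile 99.9, 18 members) and the heat shock list by 0.20 ± 0.08 (percentile 99.2, 14 members), with Hspa1a at 1.27. Genes of lipoate synthesis and the lipoate-dependent dehydrogenases shifted by 0.11 ± 0.05, with Lias at 0.02 and Dld at 0.16.

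Several of the lowest named genes at 70 nmol are transcribed mainly in liver. Albumin, Alb, was 68.4-fold lower (-6.09), with its probe on chromosome 5 from 91547772 to 91547831. At 70 nmol Alb lay at -2.90, near the lowest level well above background on that array (-3.26). The glucagon receptor Gcgr differed by -1.94. Serpina1d was at least 47.7-fold lower, Ahsg at least 38.1-fold and Fgb at least 12.7-fold, since none of these was well above background at 70 nmol. Of 42 genes on a hepatocyte list written after the arrays were seen but before its own values were, 20 were above background on the control array and not at 70 nmol. The 7 measured on both arrays differed by a median of -0.08, and 1 of them was at least 2-fold higher. The retinoic acid hydroxylase Cyp26a1 differed by -3.13 and Orm3 by -2.01, and unlike the liver genes above both were also lower at 35 nmol, by -0.80 and -1.09. Dbp, a transcription factor with a daily rhythm, was 6.89-fold higher (2.78), and the related factor Tef was 2.08 higher.

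With normexp background correction 80 genes were at least 2-fold higher and 48 lower, and the mast cell, MHC class I and NRF2 shifts were -0.75, 0.15 and 0.057, while cyclic loess gave 0.11 for MHC class I, 0.024 for NRF2 and 0.10 for heat shock, and the mean over a gene's probes gave -0.0058 for the lipoate list and -0.045 for tumour suppressors. The DNA repair shift was -0.018, -0.042 and -0.036 with normexp, quantile and cyclic loess normalisation. Scaling on spike-in RNA, chosen after seeing the data, gave 87 higher and 400 lower (17.9% higher, against 60%), because it moved the median of all genes by -0.36 at 70 nmol and by -0.42 at 35 nmol, so smaller positive differences than these turn negative under it.

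The next question was what the lower dose of 35 nmol does. Most of the named genes with the largest positive differences at 35 nmol are transcribed mainly in liver. Cyp2a5 was 3.02 higher, Serpina3k 2.64, the apolipoprotein Apoa2 2.60, the fatty acid binding protein Fabp1 2.53, Mug1 2.18, Ces1c 2.17 and the retinol carrier Rbp4 2.12, whereas Alb was 1.56 higher. On the same hepatocyte list, 13 of 26 measured genes were at least 2-fold higher (shift 1.04 ± 0.21, percentile 100). Several of these genes have close relatives, as Cyp2a5, Mug1 and the Serpina3 genes do, and their probes may bind more than 1 of them. Of 12730 measured genes, 143 were at least 2-fold higher and 38 at least 2-fold lower. Of the 143 higher genes, 68 were not well above background at 70 nmol and 23 more were at least 2-fold lower there than at 35 nmol, which left 52. Outside liver transcripts, Dbp was 4.84-fold higher (2.28), with its probe on chromosome 7 from 45577937 to 45577996, Rnase2a 2.35, Cxcl9 2.26, Cxcl10 1.95, Retnla 1.11 and Mt2 1.18.

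Red cell transcripts were the lowest at 35 nmol. The erythroid list shifted by -2.51 ± 0.20 (percentile 0), and all 4 measured members were at least 2-fold lower. The globin genes Hbb-bt and Hba-a1 differed by -2.61 and -2.50, and Alas2, the first enzyme of heme synthesis in red cells, by -2.43. Globin copies are nearly identical, so their probes cannot be assigned to 1 copy with certainty. At 70 nmol the erythroid shift was -1.11 ± 0.24. The neutrophil genes Cxcr2, S100a9 and Lcn2 differed by -2.07, -1.24 and -1.46 at 35 nmol, but Retnlg by 1.98, and the list's shift was -0.01 ± 0.33.

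Cell division genes were higher at 35 nmol by small amounts. The list of G2/M genes shifted by 0.30 ± 0.05 (percentile 100), and 22 of 23 members lay above the median of all genes, although none was 2-fold higher. Cenpe was 0.53 higher, Ccnb1 0.45 and Cdc20 0.43. The G1/S and DNA replication list shifted by 0.19 ± 0.03 (percentile 100, 24 of 25 above the median). At 70 nmol the shifts were -0.01 ± 0.04 for G2/M and 0.08 ± 0.07 for G1/S. The chemokine list shifted by 0.37 ± 0.28 (percentile 100) and alternative activation by 0.29 ± 0.18 (percentile 100). The interferon list shifted by 0.05 ± 0.09 at 35 nmol, with 1 of 31 genes, Cxcl10, at least 2-fold higher. Mast cell markers shifted by -0.80 ± 0.17 and large peritoneal macrophage markers by -0.30 ± 0.08, both at percentile 0. The NRF2, p53 and metal handling lists shifted by 0.11 ± 0.05, 0.07 ± 0.03 and 0.10 ± 0.15. The NRF2 list held 1 gene at least 2-fold higher, the glutathione transferase Gsta3 at 2.06. Gsta3 was not well above background at 70 nmol and at least 2.22-fold lower there than in the control. This is the order of the liver transcripts, highest at 35 nmol and lowest at 70 nmol. Gsta3 alone therefore does not show an oxidant response. Metal handling held 2 genes at least 2-fold higher, Mt2 at 1.18 and the iron exporter Slc40a1 at 1.22. Slc40a1 was dim on the control array (-3.34, where the lowest level well above background was -3.65). It was not well above background at 70 nmol. Hmox1 differed by 0.27, Cdkn1a by 0.40, Mt1 by 0.50, Tnf by 0.34 and Arg1 by 0.73. In the unfolded protein response list (shift -0.14 ± 0.07, percentile 0.01), Chac1, Trib3 and Asns were 1.45, 1.20 and 1.13 higher. These are targets of the transcription factor Atf4, while 13 of the 19 members lay below the median of all genes. With normexp, 55 genes were higher and 10 lower at 35 nmol, with shifts of -0.48 for mast cells, 0.056 for NRF2 and 0.13 for G1/S (0.0077 at 70 nmol), and the mean over a gene's probes gave -0.19 for large peritoneal macrophages. Spike-in scaling gave 71 higher and 251 lower (22.0% higher, against 79.0%).

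**Figure D1:**
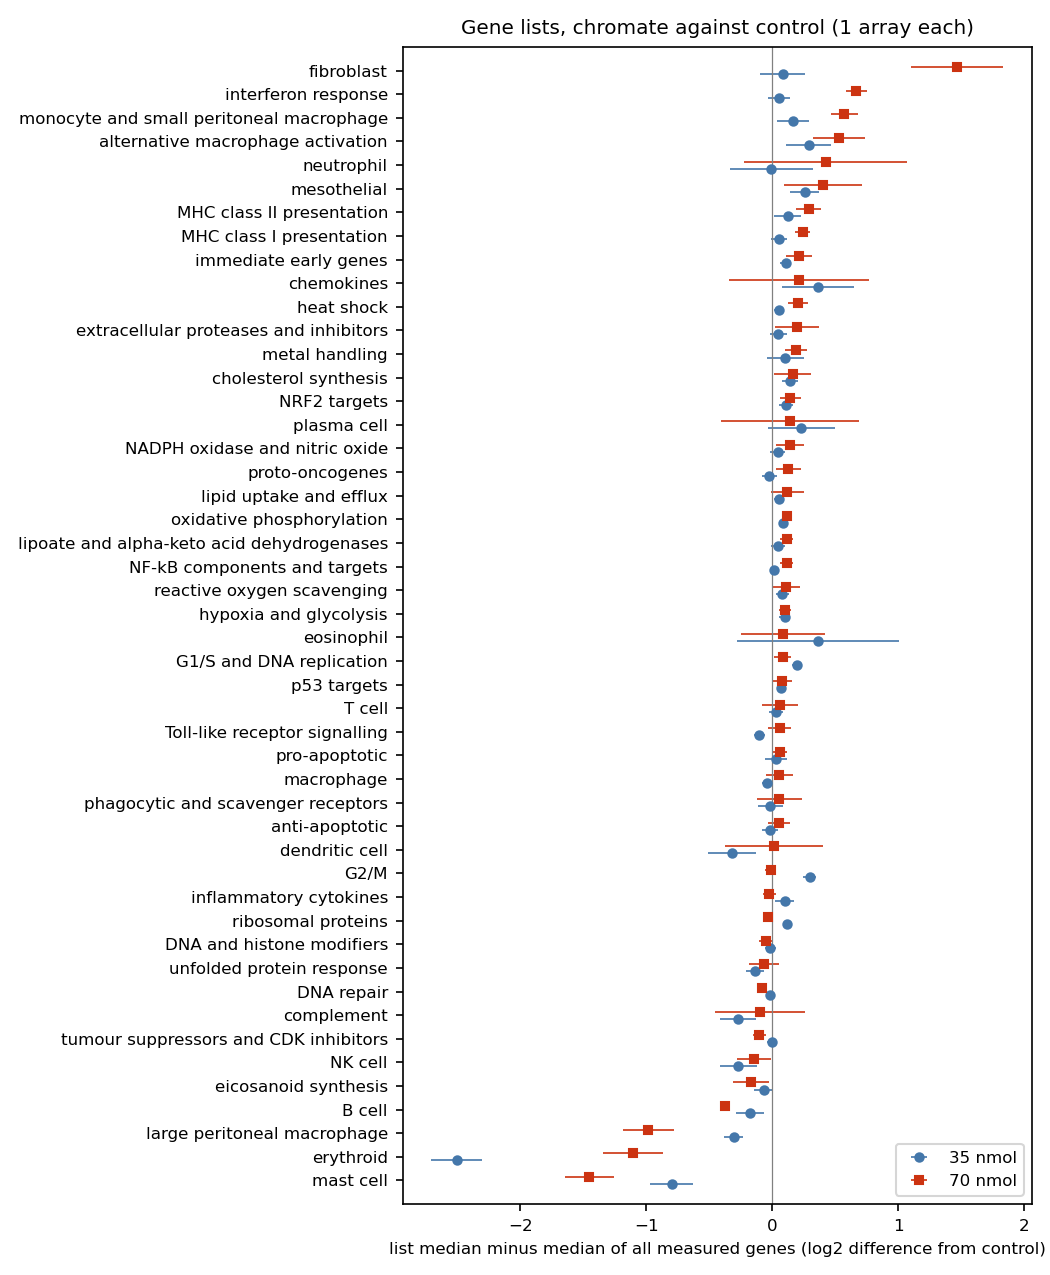
Shift of each fixed gene list with at least 3 measured members (log2 difference from the control, list median minus the median of all measured genes; bars, bootstrap SD over members; 1 array per group). The fibroblast list lies at 1.47 at 70 nmol and the erythroid list at -2.51 at 35 nmol.

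Between the doses, the 70 nmol array was higher in fibroblast and interferon response genes and lower in several genes transcribed mainly in liver. Among 12387 measured genes, 114 were at least 2-fold higher and 89 at least 2-fold lower at 70 than at 35 nmol. S100a9 was 2.26 higher, Cbr2 2.14, Fndc1 2.05, and the alpha globins Hba-a1 and Hba-a2 1.91 and 1.94. The interferon list shifted by 0.57 ± 0.06 with 5 of 31 genes at least 2-fold higher, and the fibroblast list by 1.53 ± 0.31. Alb differed by -7.65, Cyp2d26 by -3.88, Serpina3m by -3.81, Fbp1, an enzyme of gluconeogenesis, by -3.68 and Gcgr by -2.32. At 70 nmol the first of these, in order, lay at -2.90, -3.18, -3.20 and -3.08, and Gcgr at -1.88. The lowest level well above background on that array was -3.26, so differences of genes near it are uncertain in size. Fabp4 differed by -2.00. Large peritoneal macrophage markers shifted by -0.71 ± 0.21 and G2/M genes by -0.29 ± 0.04, both at percentile 0. Ribosomal protein genes shifted by -0.17 ± 0.03, and all 17 measured lay lower. The list has 44 genes on the array, so most were not measured. With quantile normalisation the ribosomal shift was -0.11. The balance turned with the looser filter on dim probes, which gave 216 higher and 244 lower. With normexp the counts were 39 higher and 20 lower, and the mean over a gene's probes gave a large peritoneal macrophage shift of -0.46.

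**Figure D2:**
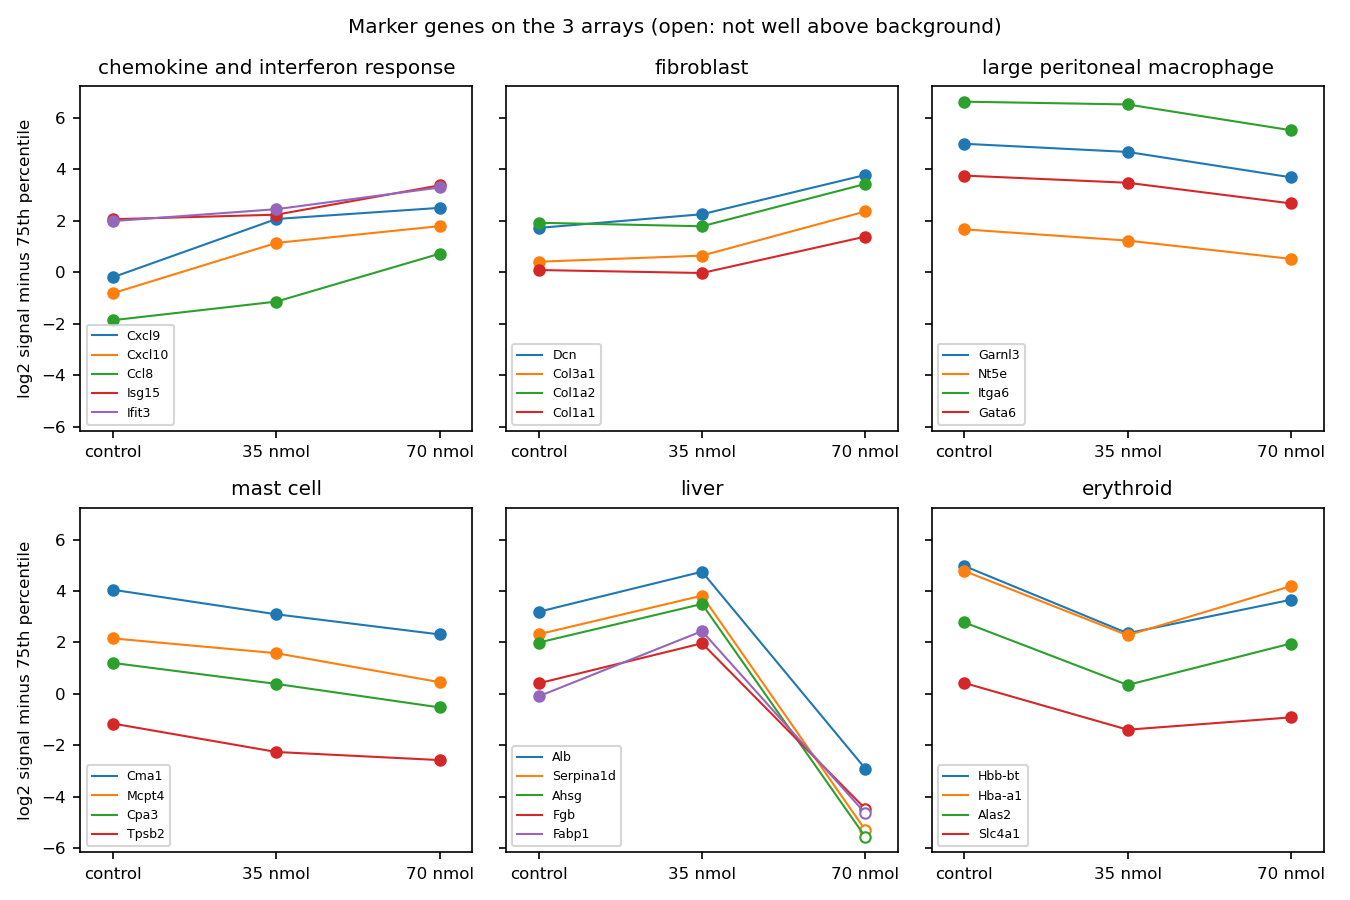
Normalised log2 signal (minus the array's 75th percentile) of named marker genes on the control, 35 nmol and 70 nmol arrays, 1 array each; open circles were not well above background. Alb lies at 3.19, 4.75 and -2.90, and Cma1 at 4.05, 3.09 and 2.31.

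Whether the doses moved the same genes was examined over the 12326 genes measured in both comparisons with the control. There, 26 genes were at least 2-fold higher at both doses, where independent lists would share 1.13, and 18 at least 2-fold lower, against 0.32. Both directions together gave 15 genes with normexp, 14 with the stricter filter on dim probes and 167 with the looser one. Spike-in scaling, chosen after seeing the data, gave 103. Simulated groups without any change shared 0 genes, but they carry only spot error, under which no unchanged gene passed 2-fold, so this gives no chance value for the overlap. Both comparisons use the same control array, which cannot be split, so part of the overlap, or all of it, may come from that array. Across genes, which are not independent replicates, the differences correlated at 0.51 (Spearman 0.52), and unchanged groups that share the control gave 0.50. The covariance was 0.052, against 0.0064 from simulated spot error, which leaves out the control sample's own deviation, so the difference does not show a shared effect of the doses. Cxcl9, Cxcl10, Dbp, Tef and Retnla were higher at both doses, and Hbb-bt, Slc4a1, C2 and Tpsb2 lower by 2-fold at both. Another Hbb-bt probe gave only -0.42 at 70 nmol.

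**Figure D3:**
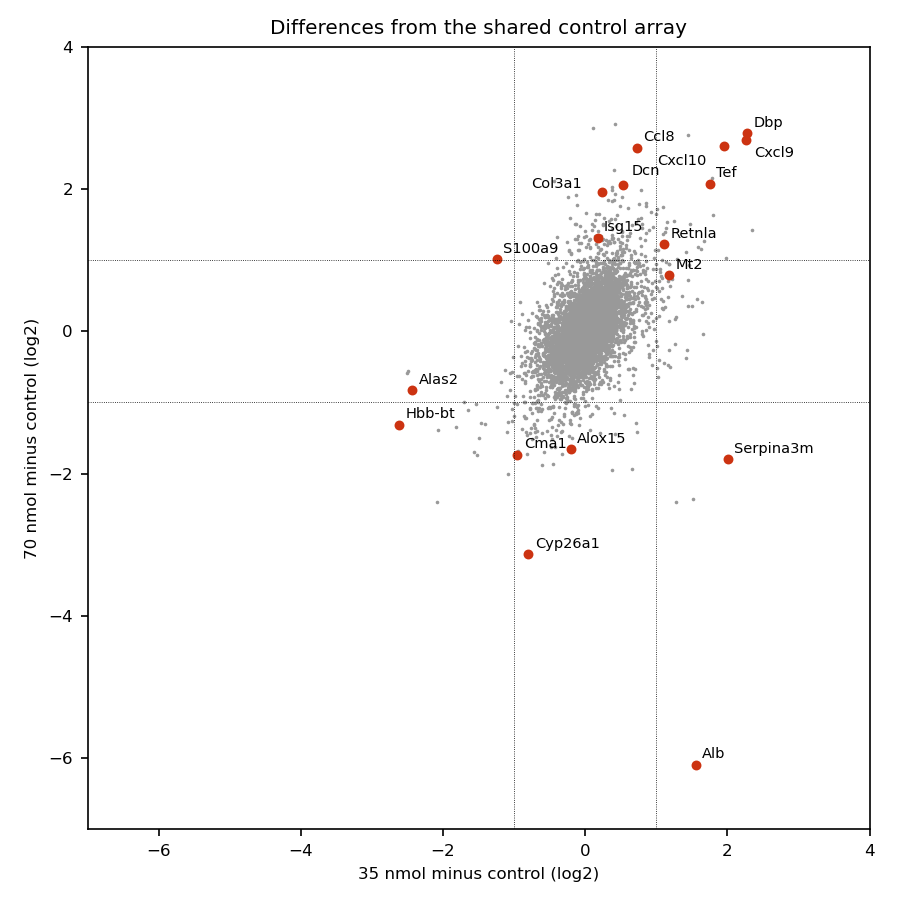
Log2 difference from the shared control array for each gene measured at both doses, 35 nmol on the horizontal and 70 nmol on the vertical axis; dotted lines mark 2-fold. Dbp lies at 2.28 and 2.78, and Alb at 1.56 and -6.09.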

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

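The test on the second hepatocyte list was set before its values were seen, and the test on genes of matching level was chosen after the result was seen. Genes are listed here because their differences from the control were at least 2-fold and of opposite sign at the 2 doses; with 1 array per group, the difference between doses was not tested.

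Alb differed from the control by -6.09 at 70 nmol and 1.56 at 35 nmol, Cyp2d26 by -2.36 and 1.52, Fbp1 by -2.40 and 1.28, and Serpina3m by -1.80 and 2.01. At 70 nmol they lay at -2.90, -3.18, -3.08 and -3.20, near the lowest level well above background on that array (-3.26). The sizes of their differences there are therefore uncertain. A general loss of dim signals at 70 nmol stays open for the dimmer liver genes. It is argued against for Alb, Serpina1d and Ahsg, which were bright on the control array. They lay at 3.19, 2.32 and 2.00 there, where the median of probes well above background was -0.02. The 9351 genes within the range of control levels of a first hepatocyte list had a median difference of 0.0036 (SD 0.57). That range, from -2.55 to 3.19, takes in bright genes, and each array was scaled on its own 75th percentile. The median therefore cannot tell whether dim signals were lost. Above background on the control array and not at 70 nmol were 1298 genes, against 308 the other way. At 35 nmol, where liver transcripts were higher, the counts were alike, 1113 against 335. A candidate explanation is RNA of liver cells in the control and 35 nmol samples, where Alb lay at 3.19 and 4.75 (log2, relative to the array's 75th percentile) against -2.90 at 70 nmol. In a second list of hepatocyte genes, 28 of the 34 members above background on the control or 35 nmol array (82.4%) had the order 35 nmol, control, 70 nmol, and under 50% would have argued against liver RNA. Of the 42 members on the array, 7 were above background at 70 nmol too and differed there by a median of -0.08 from the control, with 1 at least 2-fold higher, and by -0.75 from 35 nmol, with 6 of 7 lower, and the labels name no sort that would remove liver cells. An effect of chromate on these genes stays open and was not tested.

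S100a9, a neutrophil calcium-binding protein, differed by 1.02 at 70 nmol and -1.24 at 35 nmol.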

How the results depend on the processing

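Scaling on spike-in RNA and counts without liver and erythroid genes were chosen after seeing the data; the others were chosen before the data were examined. No paired analysis was possible because each group has 1 array, so replicates could neither be left out nor split. The 44 genes beyond 2-fold the same way at both doses and the other counts stayed within 1.5 times under quantile, median and cyclic loess scaling, the mean over a gene's probes, the deposited value table, and without liver and erythroid genes (121 higher and 34 lower at 35 nmol). The other settings moved counts, and the cause was not tested, except that a looser filter or threshold admits more genes by construction. Normexp background correction gave 80 higher and 48 lower at 70 nmol, 55 higher and 10 lower at 35 nmol, 39 higher and 20 lower between the doses, and 15 beyond the threshold the same way at both doses. The looser filter gave 321 higher and 291 lower at 70 nmol, 272 higher and 166 lower at 35 nmol, 216 higher and 244 lower between the doses, and 167 beyond the threshold the same way at both doses. The stricter filter gave 89 higher and 53 lower at 70 nmol, 40 higher and 12 lower at 35 nmol, 45 higher and 26 lower between the doses, and 14 beyond the threshold the same way at both doses. A 1.5-fold threshold gave 696 higher and 480 lower at 70 nmol, 377 higher and 245 lower at 35 nmol, 454 higher and 353 lower between the doses, and 235 beyond the threshold the same way at both doses. A 3-fold threshold gave 49 higher and 22 lower at 70 nmol, 51 higher and 12 lower at 35 nmol, 21 higher and 19 lower between the doses, and 7 beyond the threshold the same way at both doses. Spike-in scaling gave 87 higher and 400 lower at 70 nmol, 71 higher and 251 lower at 35 nmol, and 103 beyond the threshold the same way at both doses.

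Across settings, list shifts and named genes were compared after subtracting the median of all genes, so a constant scaling such as the spike-ins cannot move them there. The plain differences given for single genes do move, by -0.36 at 70 nmol and -0.42 at 35 nmol with the spike-ins, so every smaller positive difference turns negative, for example those of Hmox1, Cdkn1a and Tnf at 35 nmol and of Mt1 and Mdm2 at 70 nmol. Between the doses, the looser filter turned the balance from more genes higher to more genes lower. Under the alternatives chosen before the data were examined, 1061 list shifts stayed within 1 bootstrap SD and 80 moved; no list in the outer percentiles with a shift of at least 0.25 and no named gene beyond 2-fold changed sign. For named genes, 4772 values stayed within the spread between 2 probes and 175 moved. The counts for lists and named genes include scaling on the median of detected probes and the deposited value table. Each differs from the main scaling by about 1 constant per array, so values under these settings stayed almost by construction. The correlation between doses ranged from 0.47 to 0.54 and the covariance from 0.029 to 0.070. Normexp background correction gave shifts at 70 nmol against control of 0.057 for NRF2 targets, -0.018 for DNA repair, 0.0077 for G1/S and DNA replication, 0.15 for MHC class I presentation, 0.034 for hypoxia and glycolysis, 0.059 for oxidative phosphorylation, 0.060 for lipoate and alpha-keto acid dehydrogenases and 0.43 for monocyte and small peritoneal macrophage. Normexp background correction gave shifts at 70 nmol against control of -0.75 for mast cell. Normexp background correction gave shifts at 35 nmol against control of 0.056 for NRF2 targets, 0.0096 for reactive oxygen scavenging, -0.022 for NADPH oxidase and nitric oxide, 0.13 for G1/S and DNA replication, 0.22 for G2/M, -0.070 for tumour suppressors and CDK inhibitors, -0.038 for NF-kB components and targets and -0.024 for MHC class I presentation. Normexp background correction gave shifts at 35 nmol against control of 0.013 for heat shock, 0.037 for hypoxia and glycolysis, 0.028 for oxidative phosphorylation, 0.044 for ribosomal proteins, -0.0055 for lipid uptake and efflux, -0.091 for macrophage, -0.48 for mast cell and -0.11 for NK cell. Normexp background correction gave shifts between the doses of 0.012 for tumour suppressors and CDK inhibitors, 0.20 for NF-kB components and targets, 0.12 for MHC class II presentation, 0.017 for oxidative phosphorylation and -0.38 for mast cell. Quantile normalisation gave shifts at 70 nmol against control of -0.042 for DNA repair, 0.046 for oxidative phosphorylation, -0.080 for ribosomal proteins and -0.44 for B cell. Quantile normalisation gave shifts at 35 nmol against control of 0.021 for reactive oxygen scavenging, 0.0060 for heat shock, 0.034 for oxidative phosphorylation, 0.026 for ribosomal proteins and -0.082 for macrophage. Quantile normalisation gave shifts between the doses of -0.021 for oxidative phosphorylation and -0.11 for ribosomal proteins. Cyclic loess gave shifts at 70 nmol against control of 0.024 for NRF2 targets, -0.023 for reactive oxygen scavenging, -0.036 for DNA repair, 0.11 for MHC class I presentation, 0.10 for heat shock, -0.19 for unfolded protein response, 0.042 for hypoxia and glycolysis and 0.044 for oxidative phosphorylation. Cyclic loess gave shifts at 70 nmol against control of -0.16 for ribosomal proteins and -0.45 for B cell. Cyclic loess gave shifts at 35 nmol against control of 0.040 for NRF2 targets, -0.038 for reactive oxygen scavenging, -0.035 for NADPH oxidase and nitric oxide, 0.012 for DNA repair, 0.19 for inflammatory cytokines, -0.019 for MHC class I presentation, 0.052 for immediate early genes and -0.036 for heat shock. Cyclic loess gave shifts at 35 nmol against control of 0.016 for hypoxia and glycolysis, 0.00075 for oxidative phosphorylation, -0.028 for ribosomal proteins and -0.15 for macrophage. The looser filter gave shifts at 70 nmol against control of -0.86 for erythroid. The stricter filter gave shifts at 70 nmol against control of -1.76 for mast cell and 0.29 for T cell. The stricter filter gave shifts at 35 nmol against control of -0.059 for DNA repair and 0.035 for DNA and histone modifiers. The stricter filter gave shifts between the doses of 0.12 for metal handling, -0.045 for DNA repair, -0.068 for unfolded protein response, 0.043 for cholesterol synthesis and -0.84 for mast cell. The mean over a gene's probes gave shifts at 70 nmol against control of -0.045 for tumour suppressors and CDK inhibitors, -0.0058 for lipoate and alpha-keto acid dehydrogenases and -0.77 for large peritoneal macrophage. The mean over a gene's probes gave shifts at 35 nmol against control of -0.19 for large peritoneal macrophage and -0.074 for T cell. The mean over a gene's probes gave shifts between the doses of 0.11 for anti-apoptotic and -0.46 for large peritoneal macrophage. Signal over background limits what can be seen: 1298 genes were above background on the control array and not at 70 nmol, and 308 the other way. At 35 nmol these counts were 1113 and 335.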

Other observations

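The test on the second connective tissue list was set before its values were seen, and the other tests in this part were chosen after the results were seen.

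Further gene groups held members that differed from the control, and some of these lists lay in the outer percentiles. Cholesterol synthesis genes shifted by 0.16 ± 0.15 at 70 nmol (percentile 99.05) and 0.14 ± 0.06 at 35 nmol (percentile 99.6), with Sqle at 0.73 and 0.47 but Idi1 at -0.49 and -0.78. Complement genes went both ways at 70 nmol: Serping1 and C1s1 were 1.41 and 1.32 higher, whereas C2 and Cd55 differed by -1.09 and -1.00. Eicosanoid synthesis genes shifted by -0.17 ± 0.14 at 70 nmol (percentile 0.43), and Ptgis, which makes prostacyclin, differed by -1.19. In the lipid list, Nr1h3 was 1.03 higher and Fabp4 differed by -1.29 at 70 nmol. Egln3, an oxygen-sensing hydroxylase, differed by -1.62, while the hypoxia and glycolysis list shifted by 0.10 ± 0.05 (0.034 with normexp, 0.042 with cyclic loess).

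The other lists fixed before the data were examined are given as shifts at 70 and 35 nmol. Mesothelial markers shifted by 0.41 ± 0.31 and 0.26 ± 0.12, and plasma cell markers by 0.14 ± 0.55 and 0.23 ± 0.27. Eosinophil markers shifted by 0.09 ± 0.33 and 0.37 ± 0.64, and T cell markers by 0.06 ± 0.14 and 0.03 ± 0.05. With the stricter filter on dim probes the T cell shift at 70 nmol was 0.29. NK cell markers shifted by -0.15 ± 0.13 and -0.27 ± 0.15, and dendritic cell markers by 0.02 ± 0.39 and -0.32 ± 0.19. The neutrophil shift at 70 nmol was 0.42 ± 0.65, and the complement shifts were -0.10 ± 0.36 and -0.27 ± 0.14 (percentile 0 at 35 nmol). Lipid uptake and efflux genes shifted by 0.12 ± 0.13 and 0.06 ± 0.04, and extracellular proteases and their inhibitors by 0.20 ± 0.17 and 0.05 ± 0.07. NF-kB components and targets shifted by 0.11 ± 0.05 and 0.01 ± 0.03, with the adhesion molecule Vcam1 1.72 and 1.01 higher. Vcam1 was dim on the control array (-3.47, where the lowest level well above background was -3.65). Toll-like receptor genes shifted by 0.06 ± 0.09 and -0.10 ± 0.04. Scavenging of reactive oxygen shifted by 0.11 ± 0.11 and 0.08 ± 0.05, NADPH oxidase and nitric oxide genes by 0.14 ± 0.11 and 0.05 ± 0.06, and oxidative phosphorylation by 0.12 ± 0.04 and 0.08 ± 0.02. With cyclic loess, reactive oxygen scavenging turned to -0.023 and -0.038, and NADPH oxidase at 35 nmol to -0.035 (-0.022 with normexp). Oxidative phosphorylation fell to 0.059, 0.046 and 0.044 at 70 nmol with normexp, quantile and cyclic loess normalisation. At 35 nmol it fell to 0.028, 0.034 and 0.00075. Pro-apoptotic genes shifted by 0.06 ± 0.06 and 0.03 ± 0.09, anti-apoptotic genes by 0.05 ± 0.09 and -0.02 ± 0.06, phagocytic and scavenger receptors by 0.06 ± 0.18 and -0.02 ± 0.10, DNA and histone modifiers by -0.05 ± 0.05 and -0.01 ± 0.05, and ribosomal proteins by -0.03 ± 0.04 and 0.12 ± 0.02. Only 15 of the 44 ribosomal protein genes on the array were measured in each comparison with the control. Cyclic loess moved the ribosomal shifts to -0.16 and -0.028, and quantile normalisation and normexp gave 0.026 and 0.044 at 35 nmol. Among the other shifts given here at 35 nmol, sign also changed for NF-kB (-0.038) and lipid uptake (-0.0055) with normexp. It changed for T cell (-0.074) with the mean over a gene's probes, and for DNA and histone modifiers (0.035) with the stricter filter on dim probes. The MHC class I, heat shock and DNA repair shifts at 35 nmol were 0.05, 0.06 and -0.02. Cyclic loess turned them to -0.019, -0.036 and 0.012, and normexp turned MHC class I to -0.024. Under 3 members of the platelet, adipocyte and endothelial lists were measured, so no percentile is given for them. Of the 48 other lists, 12 lay above the 99th percentile and 5 below the 1st at 70 nmol, and 5 and 7 at 35 nmol. Lists of randomly drawn genes would give 0.48 on each side. Members of a fixed list may vary together between any 2 samples, and some lists share members. The 0.48 is therefore no chance value for these lists.

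Of 7 measured genes driven in the evening phase of the circadian clock, 6 lay above the median of all genes at both doses. Nr1d1, chosen after its values were seen, was 2.16 and 1.78 higher at 70 and 35 nmol, next to Dbp and Tef, while Arntl, of the opposite phase, differed by -0.81 and -0.67. RNA of liver cells, in which such genes cycle strongly, is argued against. The evening list's median at 70 nmol, where liver transcripts were dim, was 0.39 above that at 35 nmol, and liver RNA needed at least 1 below. The SD of 0.75 for this gap came from a separate bootstrap per dose, although both medians share the control array. Compared directly between the doses, the list's 8 measured genes had a median of 0.37 (bootstrap SD 0.09). Of these, 7 lay above the median of all genes, with Dbp and Tef among them. Both prompted the list, so their part in this result was known beforehand. A harvest at another time of day could give the pattern, and the smaller of the evening minus morning gaps at the 2 doses was 1.33, but the evening list holds Dbp and Tef, which prompted it, so this gap partly restates the pattern. The labels give no hour of harvest, and both comparisons rest on 1 control array, so harvest time and an effect of chromate cannot be told apart.

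At 70 nmol, fibroblast and monocyte markers were higher while mast cell, B cell and large peritoneal macrophage markers were lower. A lower share of resident macrophages alone would raise the markers of all other types alike. The lower mast cell and B cell markers argue against it. The range of 2.92 (bootstrap SD 0.42) between the medians of the mast cell, B cell, fibroblast and monocyte lists only restates this. These 4 lists were chosen after the results were seen. More connective tissue cells at 70 nmol could account for the fibroblast part. A second list of connective tissue genes, 2 of which are also on a fixed list, had a median of 0.98 ± 0.12 at 70 nmol, with 13 of 14 members higher, against 0.27 at 35 nmol. Expression of these genes by the macrophages themselves stays open and was not tested.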
